A study of Caenorhabditis elegans with 18 samples.

How the data were processed

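The labels describe 18 samples of total RNA from wild-type worms, labelled with biotin and hybridised to Affymetrix arrays in 4 groups: control (n = 5), H2O2 (n = 5), TRF+H2O2+TRF (n = 4) and TRF (n = 4). The submitters' processing notes name MAS5 and the Affymetrix Expression Console, with versions not given. The deposited values are intensity values, that is, MAS5 signals on a linear scale, in 1 table of 22625 probe sets by 18 arrays. On each array the mean signal without the top and bottom 2% of probe sets was about 500.1, so the arrays had been scaled to a common mean. The genome build behind the probe sets is not given in the sources used here.

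Groups and replicate numbers were taken from the sample titles. Control and H2O2 arrays numbered 5 have accessions from a later submission, and the comparisons were repeated without them. Signals were taken as log2(signal + 1) without further normalization between arrays. The 77 Affymetrix control probe sets were left out, and the 13529 of 22548 probe sets with a mean at or above the 40th percentile were kept, which lies at a geometric mean signal of 47. Gene symbols came from the table of genes of the array's probes: 12848 kept probe sets had 1 symbol, 442 had several and 239 had none here. Probe sets with several symbols were counted but their genes were not named.

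Each pair of groups was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, only the arrays of the groups compared, Benjamini-Hochberg adjusted p under 0.05, no fold minimum). The series design names H2O2 against control, TRF against control and TRF+H2O2+TRF against H2O2 and an unpaired test at p under 0.05, which is given here as the methods' t-test. TRF+H2O2+TRF against control and against TRF, and the interaction over all 18 arrays, were added. Errors of log2 fold changes are standard errors from limma, and log2 fold changes are the first group named minus the second. The groups, comparisons, tests, named genes, 38 gene lists and most alternatives were fixed before the data were examined.

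The lists covered stress responses, detoxification, immunity, lipid metabolism, protein synthesis and turnover, and markers of the tissues, germline and embryos that whole worms hold. They were tested with limma's camera with a preset correlation of 0.01 on 10286 genes, each represented by its probe set with the highest mean signal. Beside it stand camera with an estimated correlation, which called 0 lists in each of the 5 comparisons of 2 groups, limma's fry (0 lists, directional or mixed), and exact two-sided permutations of each array's mean over the list (0 lists after adjustment). The smallest p that exact permutation allows is 0.00794 for 5 against 5 arrays, 0.0159 for 4 against 5 and 0.0286 for 4 against 4. Member counts are given over all genes and adjusted over the list alone.

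Named genes followed a rule, each gene by its probe set with the highest mean signal. For the 3 comparisons of the series design these were up to 12 genes past the threshold in each direction whose groups do not overlap, or, where fewer than 5 passed, the 5 with the smallest p. For each called list the 2 members with the smallest p were named, or up to 4 past the threshold, and 11 stress and yolk genes were named whatever their result. For the other comparisons and the interaction the first part alone was used. Members that passed when adjusted over the list alone, C30E1.9 in the blocked comparison, mrpl-44 and ulp-4 in the interaction, the genes named for the block over numbers 1, 2 and 4, and the genes of the paired H2O2 comparison in the closing section were chosen after their values were seen.

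Whether replicate numbers pair the arrays was tested by correlating the residuals of arrays from different groups. For H2O2 and control the correlation of equal numbers was 0.280 to 0.681 and the best match in 5 of 5, and for TRF+H2O2+TRF and TRF 0.350 to 0.686 and the best in 4 of 4, so the blocked result is given beside these comparisons. It was -0.224 to 0.541 for TRF and control, -0.147 to 0.494 for TRF+H2O2+TRF and control, and 0.0217 to 0.327 for TRF+H2O2+TRF and H2O2, where equal numbers were the best match in 3, 3 and 2 of 4. The labels do not state what the numbers stand for.

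The pipeline was tested on simulated data with 13529 probe sets at the observed spread, of which 100 changed 2-fold and another 100 changed 4-fold in the same data. The 4-fold changes ease the adjusted threshold for the 2-fold ones, so the counts do not carry over to data with fewer changes. Between 39 and 62 of the 100 were recovered at 2-fold and between 91 and 96 at 4-fold, with 5 to 11 false calls. The noise was drawn independently for each probe set and array, so these counts do not cover deviations that real arrays share. Alternatives covered the filter, normalization between arrays, pseudocount, variance model, array weights, replicate block, the methods' t-test, the later arrays and each array left out.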

Results

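Gene expression was measured in wild-type Caenorhabditis elegans on 18 Affymetrix arrays, 1 per sample. Control worms (n = 5) were compared with worms exposed to 0.3 mM H2O2 for 2 h at the L4 larval stage (H2O2 group, n = 5). The remaining worms received a tocotrienol-rich fraction (TRF), a preparation of vitamin E compounds, throughout life (TRF group, n = 4) or from hatching to day 3 of adulthood with an H2O2 exposure in between (TRF+H2O2+TRF group, n = 4), whose dose the labels do not repeat. The values were MAS5 signals of 22625 probe sets, of which 13529 were tested. The mean correlation of an array with the other 17 ran from 0.955 to 0.971. Across 30 comparisons of hybridisation controls, 3' to 5' ratios and sperm transcripts between the groups, exact permutation tests gave a smallest adjusted p of 0.971. Single arrays differed widely all the same. The log2 mean of the sperm list ran from 6.42 in TRF replicate 4 to 8.83 in TRF replicate 2. The ubiquitin 3' to 5' ratio ran from 8.02 in TRF replicate 4 to 15.5 in control replicate 2. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits their precision.

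The first comparison asked what H2O2 did to the transcriptome. Body wall muscle genes were higher in H2O2 than in control: 15 of the 17 measured members had a higher mean signal, the median log2 fold change was 0.34, and the list mean was higher in 5 of 5 pairs of arrays with the same replicate number. Among them, tnt-2, a troponin T, had a log2 fold change of 0.54 ± 0.156 (SE) and unc-27, a troponin I, of 0.49 ± 0.149. Of the muscle genes, 6 passed when adjusted over the list alone and 0 over all genes. They were tnt-2, unc-27, pat-10 (0.34), unc-15 (0.50), mup-2 (0.75) and mlc-3 (0.45), which encode thin filament proteins, paramyosin and a myosin light chain. The list passed the competitive set test with an adjusted p of 1.79e-13, and its adjusted p was 0.540 with an estimated correlation between genes. An exact permutation of the list means of the arrays gave p = 0.0873, and exact sign flips within the pairs gave p = 0.0625, the smallest that 5 pairs allow.

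In all, 8 of 38 gene lists were called higher in H2O2 with the preset correlation and 0 lower, and each of the 8 had an adjusted p of 0.540 with an estimated correlation. Ribosomal protein genes were higher in 73 of 74 members (median log2 fold change 0.16, adjusted p = 6.24e-23), with rpl-14 at 0.28 ± 0.108 (SE) and rpl-7A at 0.23. After quantile normalization the ribosomal median was 0.00354 and the call was lost. Cuticle collagens were higher in 74 of 91 members (median 0.21, adjusted p = 2.08e-08), with col-119 at 0.28 and col-20 at 1.03. Neuronal genes, which here include the FMRFamide-like peptides, were higher in 34 of 40 members (median 0.21, adjusted p = 6.35e-06), with flp-18 at 0.48 and sng-1, a synaptic vesicle protein, at 0.92. Neuropeptide-like nlp genes were higher in 38 of 47 members (median 0.13, adjusted p = 3.21e-05), with nlp-11 at 0.50 and nlp-9 at 0.42. Pharyngeal genes were higher in 11 of 11 members (median 0.27, adjusted p = 0.00651), with myo-2, a pharyngeal myosin, at 0.46 and pqn-74 at 0.58. Oocyte and eggshell genes were higher in 20 of 21 members (median 0.093, adjusted p = 0.00203), with pos-1 at 0.15 and cpg-2 at 0.13. The 5 vitellogenins, which encode yolk proteins, were all higher (median 0.11, adjusted p = 0.0230), with vit-6 at 0.21 and vit-5 at 0.15. The oocyte list lost its call after quantile normalization, and the vitellogenin median turned to -0.0282. The oocyte and vitellogenin calls were also lost with median centring, and the pharynx and vitellogenin calls without the signal filter. The muscle, ribosomal, collagen and neuronal calls held with each array left out. The nlp call was lost without H2O2 replicate 4 (median 0.029), the pharynx call without H2O2 replicate 1 (0.11) or control replicate 5 (0.17), the oocyte call without H2O2 replicate 2 (0.088) or 5 (0.051), and the vitellogenin call without control replicates 1, 3 or 5 or H2O2 replicates 2 or 5 (0.093 to 0.12). The number of called lists was 14 without control replicate 4 and 13 without H2O2 replicate 5.

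Gene by gene, 0 of the 13529 probe sets passed between H2O2 and control in limma, and the methods' t-test after Benjamini-Hochberg adjustment also gave 0. At an unadjusted p under 0.05, limma gave 317 and the methods' t-test 401 probe sets, where 676 would be expected by chance. The 2 groups did not overlap in 64 probe sets (0.473%), and chance gives 0.794%. The genes with the smallest p included C29F5.1, with signals of 798 ± 189 (SD, n = 5) in control and 1461 ± 157 (n = 5) in H2O2 (log2 fold change 0.90 ± 0.167). The other 4 with a higher mean in H2O2 were oig-2 (0.64), C17H12.10 (1.5), cex-1, a calcium-binding protein (0.85), and F42A10.7 (0.86). Those with a lower mean were the homeobox gene tab-1 (-0.94), the sugar transporter gene swt-3 (-0.84), baz-2 (-0.64), the TGF-beta family gene unc-129 (-0.67) and H20E11.3 (-0.67), and a further probe set of baz-2 had the opposite sign. With the replicate number as a block, since the numbers pair these arrays, 0 probe sets passed, the smallest adjusted p was 0.108, and 1287 had an unadjusted p under 0.05. The pairs were not matched in sperm transcripts. The mean of the sperm list differed, H2O2 minus control, by -0.775 log2 in number 2 and by 1.49 in number 4. The blocked set test called 11 lists, and its smallest adjusted p was 0.386 with an estimated correlation.

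The classical oxidative stress genes did not pass between H2O2 and control, and each adjusted p was 1.0. The superoxide dismutase gene sod-3 had a log2 fold change of 0.19, the glutathione S-transferase gene gst-4 of -0.29, the glutathione synthesis gene gcs-1 of 0.10 and the catalase gene ctl-2 of -0.10. Among the chaperones, hsp-16.2 had 0.50 ± 0.636, with signals from 376 to 5556 among the 5 H2O2 arrays, while hsp-4 of the endoplasmic reticulum had 0.19 and mitochondrial hsp-6 had 0.07. The metallothionein gene mtl-1 had -0.48, the transcription factor genes daf-16 and skn-1 had 0.08 and -0.26, and the yolk protein gene vit-2 had 0.07. A further probe set of gcs-1, and 1 of the 2 further ones of daf-16 and of skn-1, had the opposite sign. The antioxidant enzyme list had a median of 0.033 over 29 genes (adjusted p = 0.293), and the heat shock list 0.10 over 21 genes (adjusted p = 0.0881). The list of phase II genes downstream of SKN-1 had a median of 0.00769 (adjusted p = 0.842). In the glutathione S-transferase list the median was -0.000986 while the mean was 0.0277.

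The second comparison asked what TRF alone did. F42A10.7 rose 5.21-fold in TRF, from a mean signal of 290 ± 66.0 (SD, n = 5) in control to 1503 ± 313 (n = 4), with a log2 fold change of 2.38 ± 0.215 (SE) and an adjusted p of 0.00143. Its signals ran from 176 to 345 in control and from 1100 to 1853 in TRF. In H2O2 they ran from 363 to 632, and in TRF+H2O2+TRF 3 arrays had 916 to 1427 while replicate 4 had 243. Under the limma alternatives its adjusted p ran from 0.000124 to 0.0403, and the methods' t-test gave 0.312 after adjustment. It was the only probe set of 13529 to pass in limma, where 474 had an unadjusted p under 0.05 and 676 would be expected by chance. The methods' t-test gave 561 unadjusted (283 higher and 278 lower in TRF) and 0 after adjustment. Without TRF replicate 2, and with each array centred on its median, 2 probe sets passed, and the second of them carries several gene symbols.

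**Figure D1:**
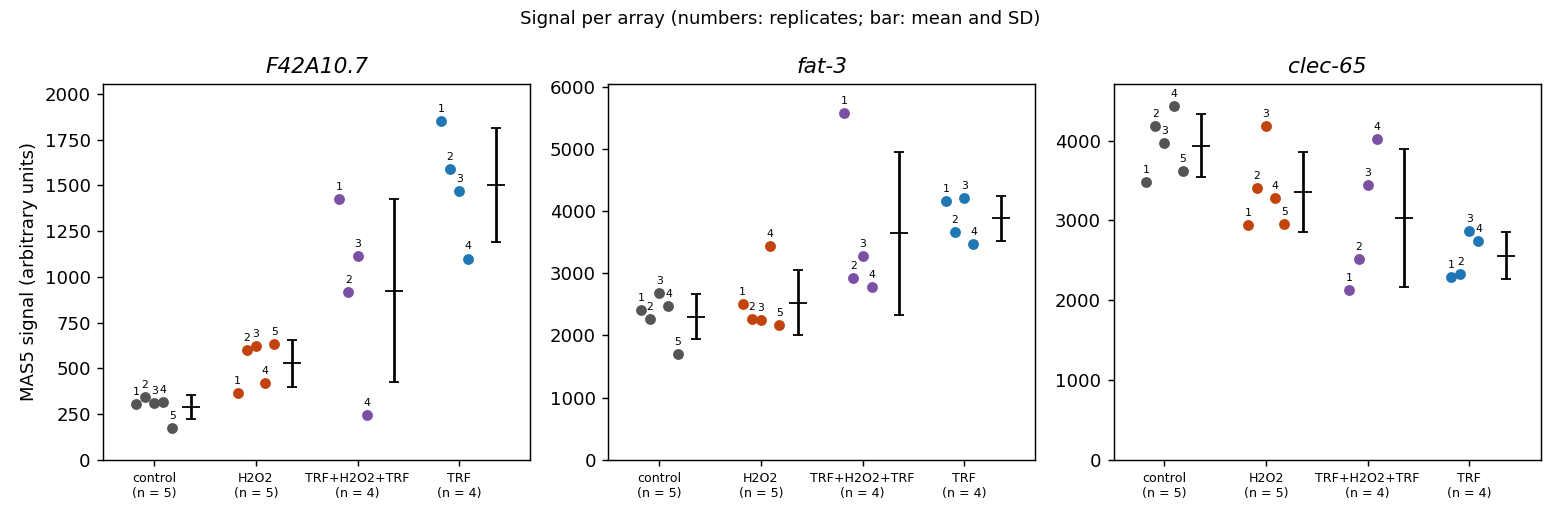
MAS5 signal (arbitrary units) of F42A10.7, fat-3 and clec-65 on each array by group, with replicate numbers beside the points and bars for the mean and SD. F42A10.7 lies at 1100 to 1853 in TRF and at 176 to 345 in control, and TRF+H2O2+TRF replicate 4 has 243.

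The genes next in the TRF comparison did not pass over all genes, nor did they with the replicate number as a block over numbers 1 to 4, where F42A10.7 alone passed and 899 had an unadjusted p under 0.05. With that block and number 3 left out as well, chosen after the data were seen, 25 probe sets passed (16 higher, 9 lower), with fat-3 (0.66, adjusted p = 0.0419), F07C3.9 (0.87), clec-70 (1.53), thn-1 (1.13) and clec-65 (-0.71) among them. Arrays numbered 1, 2 and 4 match best between the groups (residual r 0.302 to 0.541), while those of number 3 do not (-0.224). The polyunsaturated fatty acid desaturase gene fat-3 had 2305 ± 366 in control (SD, n = 5) and 3882 ± 368 in TRF (n = 4), a log2 fold change of 0.76 ± 0.133 (SE) with an adjusted p of 0.301, and it passed when adjusted over the list alone among 20 genes of fatty acid synthesis. That list as a whole pointed down without passing (13 of 20 lower, median -0.080, adjusted p = 0.225). Of the 66 C-type lectins, 5 passed when adjusted over the list alone and 0 over all genes: clec-70 (1.67) and clec-5 (1.51) were higher in TRF, and clec-65 (-0.62), clec-186 (-0.61) and clec-66 (-0.86) were lower. The lectin list as a whole had a median of -0.067, a mean of 0.00674 and a test pointing down that was not past the threshold (adjusted p = 0.0694). The ferritin gene ftn-1 (0.90) passed when adjusted over the list alone among 7 metal response genes. Further genes with small p were F07C3.9 (0.89, adjusted p = 0.301), the thaumatin-like gene thn-1 (1.35, 0.608), F54E2.1 (-0.86, 0.427), cdr-2 (-0.57, 0.909) and K12H4.7 (-0.56, 0.995).

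Among the fixed lists, 3 of 38 were called in TRF, and each had an adjusted p of 0.859 with an estimated correlation. Proteasome subunit genes were lower in 29 of 33 members (median log2 fold change -0.11, adjusted p = 3.29e-05), with pas-3 at -0.23 and pas-2 at -0.18. An exact permutation of the proteasome list means gave p = 0.0397 (adjusted p = 0.873). Glutathione S-transferases were lower in 22 of 31 members (median -0.097, adjusted p = 0.0282), with gst-5 at -0.40 and gst-27 at -0.28. UDP-glucuronosyltransferases, enzymes of xenobiotic conjugation, were higher in 33 of 45 members (median 0.13, adjusted p = 0.0367), with ugt-1 at 0.96 and ugt-25 at 0.60, and lost the call after quantile normalization (median 0.049). The proteasome call held with each array left out, while the glutathione S-transferase call was lost without control replicate 4 (-0.086) or TRF replicate 3 (-0.079), and the UDP-glucuronosyltransferase call without control replicates 2 or 3 or TRF replicates 1 or 3 (0.048 to 0.12). The stress genes named above had adjusted p-values from 0.995 to 0.998 in TRF: hsp-16.2 had 0.57, gcs-1 0.28, hsp-4 0.11, hsp-6 0.10, skn-1 0.06, daf-16 0.05, ctl-2 -0.01, vit-2 -0.02, gst-4 -0.04, sod-3 -0.17 and mtl-1 -0.29, and 1 of the 2 further probe sets of skn-1 had the opposite sign. The groups did not overlap in 160 probe sets (1.18%), and chance gives 1.59%. The number of called lists was 11 without control replicate 1, 7 without control replicate 2, 5 without control replicate 4, 9 without control replicate 5, and 9, 7 and 8 without TRF replicates 2, 3 and 4.

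The third comparison asked how TRF given before and after H2O2 changed the state of H2O2-exposed worms. All 74 ribosomal protein genes had lower means in TRF+H2O2+TRF than in H2O2 (median log2 fold change -0.19, adjusted p = 2.58e-44), with rps-25 at -0.31 ± 0.0859 (SE) and rps-29 at -0.29. The ribosomal list had an adjusted p of 0.493 with an estimated correlation, and after quantile normalization its median was -0.00517 and the call was lost. Cuticle collagens were lower in 71 of 91 members (median -0.20, adjusted p = 1.65e-07, and 0.622 with an estimated correlation), with col-119 and col-122 both at -0.29. Nuclear hormone receptor genes were higher in all but 30 of 134 members (median 0.17, adjusted p = 0.000176, and 0.622 with an estimated correlation), with nhr-154 at 0.51 and nhr-182 at 0.44. UDP-glucuronosyltransferases were higher in 37 of 45 members (median 0.19, adjusted p = 0.00291, and 0.682 with an estimated correlation), with ugt-25 at 0.47 and ugt-51 at 0.82. The collagen call was lost without H2O2 replicate 1 (-0.13), that of the receptors without TRF+H2O2+TRF replicate 1 (0.073) and that of the UDP-glucuronosyltransferases without H2O2 replicates 2 or 3 or TRF+H2O2+TRF replicate 3 (0.082 to 0.12), and the last 2 were also lost without the signal filter.

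The oocyte, germline, vitellogenin and intestine lists were called lower in TRF+H2O2+TRF than in H2O2 with 0 members past the threshold, and the adjusted p of each of these 4 lists was 0.402 or 0.622 with an estimated correlation. Sperm genes (30 of 42 lower, adjusted p = 0.0529) and embryonic zygotic genes (10 of 17 higher, adjusted p = 0.971) did not pass. Oocyte and eggshell genes were lower in 20 of 21 members (median -0.15, adjusted p = 6.93e-07), with cbd-1 at -0.25, whose further probe set had the opposite sign, and perm-4 at -0.22, and germline genes in 16 of 20 (median -0.14, adjusted p = 0.00291), with gld-1 at -0.21 and pgl-3 at -0.32. The 5 vitellogenins were all lower (median -0.18, adjusted p = 0.00122), with vit-6 at -0.24 and vit-4 at -0.18. Intestinal genes were lower in 10 of 14 members (median -0.13, adjusted p = 0.0158), with the protease genes asp-3 at -0.25 and asp-1 at -0.24. After quantile normalization the oocyte and intestine calls were lost, and the vitellogenin median turned to 0.0193. Proteasome genes (median -0.11, 27 of 33 lower, adjusted p = 0.000176), with pas-4 at -0.26 and pbs-1 at -0.20, and glutathione S-transferases (median -0.10, 20 of 31 lower, adjusted p = 0.0251), with gst-44 at -0.54 and gst-12 at -0.47, were called lower as well. Their adjusted p was 0.622 with an estimated correlation. Genes repressed by DAF-16 were lower in 6 of 8 members (median -0.22, adjusted p = 0.00291, and 0.402 with an estimated correlation), with dod-17 at -0.70 and vit-5 at -0.20. C-type lectins were lower in 41 of 66 members (median -0.062, adjusted p = 0.0404, and 0.674 with an estimated correlation), with clec-63 at -0.27 and clec-258 at -0.74. Respiratory chain genes were lower in 28 of 38 members (median -0.056, adjusted p = 0.0460, and 0.622 with an estimated correlation), with the succinate dehydrogenase genes mev-1 at -0.17 and sdhb-1 at -0.15. The DAF-16, lectin and respiratory calls were lost after quantile normalization, and these, the intestine call and the glutathione S-transferase call without the signal filter. The oocyte and vitellogenin calls held with each array left out. Without TRF+H2O2+TRF replicate 1, 6 lists were called in place of 13, and the germline (-0.090), proteasome (-0.069), glutathione S-transferase (-0.045), DAF-16 (-0.089), lectin (-0.063) and respiratory (-0.066) calls were lost. Further losses were the germline call without TRF+H2O2+TRF replicate 4 (-0.073) or H2O2 replicate 5 (-0.067), the intestine call without H2O2 replicates 1 or 4 or TRF+H2O2+TRF replicates 2 or 3 (-0.14 to -0.025), the glutathione S-transferase call without H2O2 replicates 3 or 4 or TRF+H2O2+TRF replicate 3 (-0.083 to -0.068), the lectin call without H2O2 replicates 1, 3 or 4 or TRF+H2O2+TRF replicates 2 or 3 (-0.085 to -0.031), and the respiratory call without H2O2 replicates 2 or 5 or TRF+H2O2+TRF replicates 2 or 3 (-0.067 to -0.021).

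**Figure D2:**
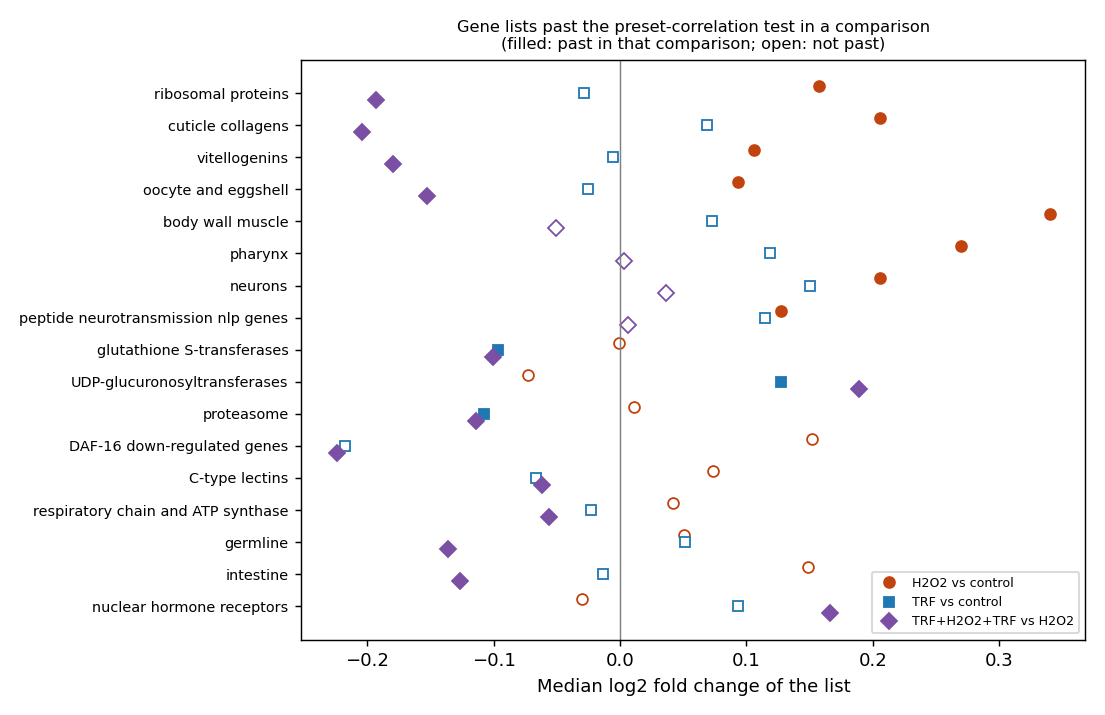
Median log2 fold change of each fixed gene list called in at least 1 of the 3 comparisons of the study design, with filled symbols where the list passed the set test with a preset correlation. The ribosomal median is 0.16 in H2O2 against control and -0.19 in TRF+H2O2+TRF against H2O2, and both calls are lost after quantile normalization.

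Body wall muscle genes, which were higher in H2O2 than in control, did not pass between TRF+H2O2+TRF and H2O2 (median -0.05, adjusted p = 0.339). Gene by gene, 0 probe sets passed in limma and 0 in the methods' t-test after adjustment, with 302 and 366 at an unadjusted p under 0.05. The groups did not overlap in 130 probe sets (0.961%), and chance gives 1.59%. The smallest p-values belonged to F42C5.9 (log2 fold change 0.74), C03B1.13 (0.87), baz-2 (0.56), wrk-1 (0.94) and the aquaporin gene aqp-1 (1.05) with higher means in TRF+H2O2+TRF, and to the patched-related gene ptr-17 (-1.24), the COP9 signalosome gene csn-2 (-1.24), rps-25, col-119 and rps-29 with lower means. The signals of aqp-1 were 772 ± 291 in H2O2 (SD, n = 5) and 1625 ± 765 in TRF+H2O2+TRF (n = 4). A further probe set of baz-2 had the opposite sign. The stress genes had adjusted p-values of 1.0: skn-1 had 0.32, ctl-2 0.14, mtl-1 0.12, gst-4 0.05, hsp-6 0.04, gcs-1 0.03, sod-3 -0.06, vit-2 -0.07, hsp-16.2 -0.08, daf-16 -0.09 and hsp-4 -0.26. A further probe set of hsp-6, and 1 of the 2 further ones of daf-16 and of skn-1, had the opposite sign.

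**Figure D3:**
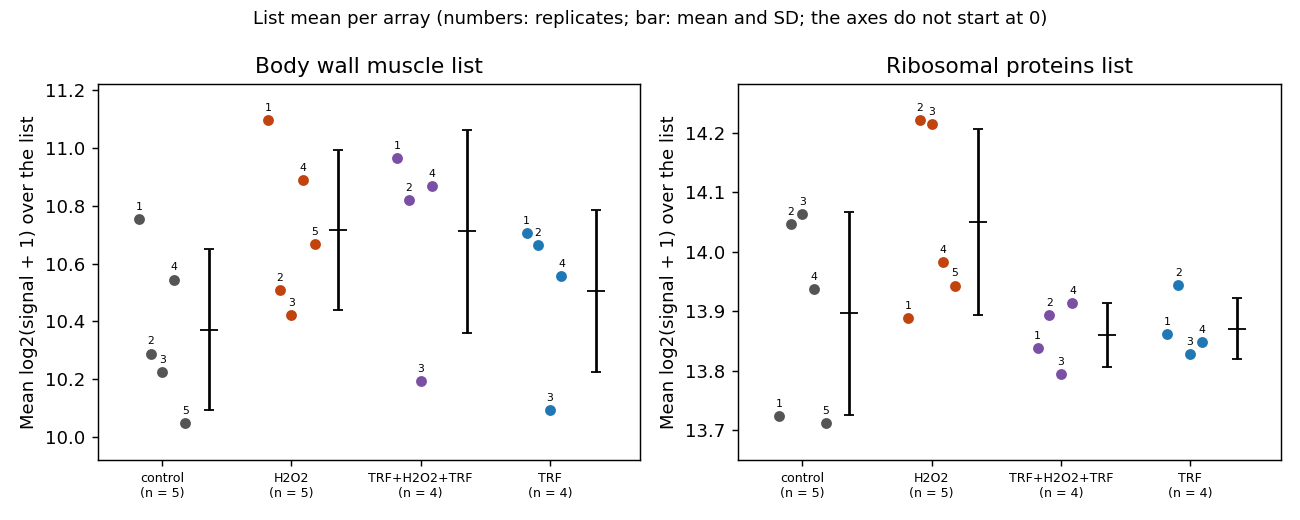
Mean log2(signal + 1) over the body wall muscle list and over the ribosomal protein list on each array by group, with replicate numbers beside the points, bars for the mean and SD, and axes that do not start at 0. The muscle mean is higher in H2O2 than in the control array of the same number in 5 of 5 pairs, and higher in TRF+H2O2+TRF than in TRF in 4 of 4 pairs.

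Against control, TRF+H2O2+TRF had higher muscle and neuronal genes, and the adjusted p was 0.757 or 0.835 with an estimated correlation for each of the 8 lists called. Body wall muscle genes were higher in 15 of 17 members (median log2 fold change 0.32, adjusted p = 2.42e-06), neuronal genes in 37 of 40 (median 0.25, adjusted p = 4.60e-06), and nlp genes in 32 of 47 (median 0.21, adjusted p = 0.00171). Nuclear hormone receptors were higher in 99 of 134 members (median 0.12, adjusted p = 0.00296) and UDP-glucuronosyltransferases in 35 of 45 (median 0.14, adjusted p = 0.0150), and both lost the call after quantile normalization and without the signal filter. Other detoxification lists did not pass: glutathione S-transferases were lower in 19 of 31 members (median -0.10, adjusted p = 0.139), cytochrome P450 genes had an adjusted p of 0.291 and the phase II genes downstream of SKN-1 of 0.967. Proteasome genes were lower in 29 of 33 members (median -0.089, adjusted p = 8.30e-05), DNA replication genes in 21 of 29 (median -0.081, adjusted p = 0.00233) and ribosomal protein genes in 61 of 74 (median -0.033, adjusted p = 0.0128), the last with a median of 0.00383 after quantile normalization. In limma 0 probe sets passed, with 384 at an unadjusted p under 0.05, and the methods' t-test gave 444 unadjusted and 0 adjusted. The smallest p-values belonged to T22F3.11 (2.32), the bestrophin gene best-1 (0.93), glo-3 (0.79), nrf-5 (0.68) and C17H12.10 (1.48) with higher means, and to tab-1 (-1.44), dct-13 (-0.61), the splicing factor gene rsp-6 (-0.39), F54E2.1 (-0.60) and fbxb-84 (-0.81) with lower means. Leaving out control replicate 4 made 1 probe set pass, that of T22F3.11, and leaving out TRF+H2O2+TRF replicate 4 made 1 pass, that of F42A10.7. The muscle and neuronal calls held with each array left out. The number of called lists was 15 without control replicate 1 and 3 without TRF+H2O2+TRF replicate 1, where the proteasome (-0.055), DNA replication (-0.069), nlp (0.11), receptor (0.061) and ribosomal (-0.028) calls were lost. Without control replicate 5 the DNA replication (-0.018), nlp (0.13) and receptor (0.065) calls were lost, and without TRF+H2O2+TRF replicate 4 the nlp call (0.17). The UDP-glucuronosyltransferase call was lost without control replicates 2 or 3 or TRF+H2O2+TRF replicates 3 or 4 (0.056 to 0.16), and the ribosomal call without control replicates 2, 3 or 4 or TRF+H2O2+TRF replicate 3 (-0.026 to 0.0053). The groups did not overlap in 139 probe sets (1.03%), and chance gives 1.59%.

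TRF+H2O2+TRF and TRF differ in the H2O2 exposure and, by the labels, in the TRF schedule: between them, 14 of 17 body wall muscle genes were higher in TRF+H2O2+TRF (median log2 fold change 0.28, adjusted p = 0.000305, and 0.890 with an estimated correlation). Of the hydrogen sulphide and hypoxia genes, 5 of 7 were higher (median 0.21, adjusted p = 0.0105, and 0.808 with an estimated correlation), and cysl-2 (0.47) passed when adjusted over the list alone, with 0 passing over all genes. Histone genes were lower in 22 of 23 members (median -0.095, adjusted p = 0.000492, and 0.808 with an estimated correlation). The muscle call was lost without TRF+H2O2+TRF replicate 1 (median 0.20) or TRF replicate 3 (0.060), the hypoxia call without TRF+H2O2+TRF replicate 2 or TRF replicates 2 or 3 (0.10 to 0.28), and the histone call without TRF replicate 2 (-0.040). In limma 0 probe sets passed, with 198 at an unadjusted p under 0.05, and the methods' t-test gave 251 unadjusted and 0 adjusted. The smallest p-values belonged to F57H12.6 (-1.64, adjusted p = 0.419), ora-1 (-1.25, 0.419), the antimicrobial peptide gene cnc-4 (-0.53), W10G11.2 (-0.77) and the lipase gene lips-14 (-0.90) with lower means, and to rog-1 (1.04), fnip-2 (0.80), Y76B12C.6 (1.01), F26A3.4 (0.55) and ddo-2 (0.54) with higher means. The groups did not overlap in 148 probe sets (1.09%), and chance gives 2.86%. With the replicate number as a block, since the numbers pair these arrays, 1 probe set passed, that of C30E1.9 (1.79 ± 0.162, adjusted p = 0.0361), while 0 passed with number 3 left out as well (700 at an unadjusted p under 0.05, smallest adjusted p 0.224), and 7 lists were called, with a smallest adjusted p of 0.617 with an estimated correlation. Mean signals of C30E1.9 were 869 ± 242 in control (SD, n = 5), 568 ± 408 in H2O2 (n = 5), 1128 ± 569 in TRF+H2O2+TRF (n = 4) and 347 ± 236 in TRF (n = 4). The blocked lists higher in TRF+H2O2+TRF were muscle (adjusted p = 4.09e-10), neurons, nlp genes, hydrogen sulphide and hypoxia (each 0.0203), and antioxidant enzymes (0.0242). Histones (median -0.095, adjusted p = 0.000415) and germline (-0.12, 0.0203) were lower. The number of lists called without the block was 12 and 6 without TRF+H2O2+TRF replicates 3 and 4, and 11, 5 and 10 without TRF replicates 1, 2 and 4.

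Whether the TRF response differed between worms with and without H2O2 was tested as an interaction over all 18 arrays, where the TRF schedules also differ. In limma 0 probe sets passed, with 154 at an unadjusted p under 0.05, and no other tool was run for it. With each gene taken by its probe set of highest mean signal, the 5 genes with the smallest p on each side were C30E1.9 (2.80), Y51B9A.8 (1.23), rog-1 (1.20), fnip-2 (1.14) and soap-1 (0.65) on the positive side, and csn-2 (-1.96), F42A10.7 (-1.79), ptr-17 (-1.41), M151.4 (-1.39) and the prolyl carboxypeptidase gene pcp-1 (-0.75) on the negative side, each with an adjusted p of 1.0. Dimmer probe sets of other genes had small p as well, such as mrpl-44 (-0.91) and ulp-4 (2.34), and a further probe set of soap-1 had the opposite sign. A difference of the F42A10.7 response between the H2O2 states was thus not past the threshold, and was -1.24 (adjusted p = 1.0) without TRF+H2O2+TRF replicate 4.

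Fold changes of H2O2 against control and of TRF+H2O2+TRF against H2O2 had a Pearson r of -0.458 across 10286 genes, which are not independent replicates. These comparisons share the H2O2 arrays, and simulated groups with no change gave a mean r of -0.470 (-0.499 to -0.435). The simulation drew each gene and array independently, while the real arrays share deviations. Its narrow range therefore shows the effect of sharing arrays and is no reference for the spread by chance. With the H2O2 arrays split between the comparisons, the median r of 20 splits was 0.133 (-0.143 to 0.451). Fold changes of H2O2 and of TRF against the shared control arrays had an r of 0.349, where groups simulated in the same way gave 0.474. Splitting the control arrays gave a median r of -0.144 (-0.280 to -0.0219). These splits take no account of the replicate numbers. Control and H2O2 arrays of equal number deviate together (residual r 0.280 to 0.681) and enter different comparisons after the split. That alone can raise the r with split H2O2 arrays and lower the r with split control arrays. Neither split therefore decides how the responses relate.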

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

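The tests of the labelling batch, sperm content, array brightness, bright probe sets, RNA integrity, shared H2O2 arrays and TRF+H2O2+TRF replicate 4, the splits for the TRF effect over all 18 arrays and the splits of lists that part every pair, were chosen only after those results were seen, while the other splits of the arrays were planned.

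In 26 of 388 groups of arrays, 1 array stood apart from the rest by more than Dixon's critical value for the gap to its neighbour over the group's range, where chance gives about 19.4. TRF replicate 3 stood apart for oig-2 (0.920), H20E11.3 (0.841), nlp-11 (0.917) and the means of the neuron list (0.884) and the nlp list (0.832). TRF+H2O2+TRF replicate 3 stood apart for oig-2 (0.833), cex-1 (0.960) and tab-1 (0.834). Control replicate 5 stood apart for cex-1 (0.845), F42A10.7 (0.813), swt-3 (0.722), clec-70 (0.778) and the oocyte and eggshell list (0.812), and H2O2 replicate 5 for col-119 (0.756) and ugt-25 (0.715). TRF replicate 1 stood apart for hsp-6 (0.859), ctl-2 (0.853) and the respiratory chain list (0.842), and TRF+H2O2+TRF replicate 4 for ugt-25 (0.834) and gst-12 (0.841). The remaining gaps were tab-1 in control replicate 2 (0.716), col-20 in control replicate 1 (0.761), hsp-6 in control replicate 4 (0.740), F07C3.9 in TRF+H2O2+TRF replicate 1 (0.843), gst-44 in H2O2 replicate 2 (0.761) and gst-12 in control replicate 3 (0.721).

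Arrays numbered 3 of TRF and TRF+H2O2+TRF deviated from their group means in the same genes as arrays numbered 5 of control and H2O2 (residual r 0.377 to 0.523), and not like control and H2O2 arrays numbered 3 (-0.224 to 0.0217). A shared sperm content is argued against by a span of 1.62 log2 units in the mean of the sperm list over these 4 arrays. A shared worm stage or oocyte content stays open. The oocyte and eggshell means of the 4 arrays were 12.653 to 12.79, above those of all other arrays (12.293 to 12.648). A labelling batch that crosses the replicate numbers may account for the pattern: the lowest signal of the dap labelling spike-in on the 4 arrays was 1.29 times the highest of control and H2O2 replicate 3. The 4 arrays lay at 165 to 258, control and H2O2 replicate 3 at 109 and 128, and numbers 1 and 2 at 75.5 to 126, while number 4 lay at 159 to 183 apart from H2O2 replicate 4 at 89.8, so a high spike-in signal is not particular to the 4 arrays. No biological explanation other than the sperm content was tested, and the labels give no batch.

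The ribosomal protein list was higher in H2O2 than in control by 0.154 ± 0.0305 (SE over 5 pairs of the same number, log2), in 5 of 5 pairs, and lower in TRF+H2O2+TRF than in H2O2. RNA integrity stays open. Over these pairs the shift at no difference in the 3' to 5' ratio was 1.01 times that without it (0.156 ± 0.0611). Its SE grew from 0.0305 to 0.0611, too wide for a regression on 5 pairs to decide. Without pairing this shift was 1.35 times that without the ratio (0.208 ± 0.0877). Overall array brightness as measured by the hybridisation controls stays open too, with 0.994 times over these pairs (0.153 ± 0.0433). Over the arrays without pairing, the shift went from 0.154 ± 0.104 to 0.117 ± 0.0719 (0.763 times) with these controls, which does not decide it. A shift of bright probe sets may account for the pattern: 35 other genes in the same range of mean signal shifted by 0.141 ± 0.0370, which is 0.918 times the shift of the list, and the list exceeded them by 0.0126 ± 0.0152. Quantile normalization brought the median from 0.16 to 0.00354. Whether the opposite signs come from the H2O2 arrays shared by both comparisons stays open: with these arrays split between the comparisons the share of splits with opposite signs was 1 (20 of 20), but of 121 simulated cases with no group difference and shifts as large, 87.6% gave the same. H2O2 itself stays open as an untested biological explanation.

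Other splits of the same arrays into groups of the same sizes were compared with the real groups. For TRF against control 6 of 100 splits gave as many probe sets (real 1, highest other 517), so chance cannot be excluded for this count. Where the real count is 0 every split gives as many by construction, which tests nothing: 100 of 100 splits for H2O2 against control (real 0, highest other 1297), 100 of 100 for TRF+H2O2+TRF against H2O2 (real 0, highest other 177) and against control (real 0, highest other 1), 35 of 35 against TRF (real 0, highest other 10), and 100 of 100 random assignments for the interaction (real 0, highest other 1) and for the TRF effect over all 18 arrays (real 0, highest other 566). For lists chance cannot be excluded for TRF against control, with as many in 97 of 100 splits (real 3, highest other 20), for TRF+H2O2+TRF against H2O2, 26 of 100 (real 13, highest other 18), and against control, 75 of 100 (real 8, highest other 19). The numbers pair the arrays of H2O2 with control and of TRF+H2O2+TRF with TRF, and there the 71 of 100 splits (real 8, highest other 17) and 34 of 35 (real 3, highest other 18) with as many lists include splits that put whole pairs on 1 side. Of the 16 and 8 splits that part every pair, 7 and 7 gave as many lists (highest other 11 and 11), and with the replicate block 4 (real 11, highest other 12) and 3 (real 7, highest other 11). Splits with 177 to 1297 calls point to a structure of the samples that crosses the treatments. The highest split of H2O2 and control put both arrays numbered 1 and both numbered 5 on the same side with control replicate 4. That of TRF and control joined control replicates 1 and 5 with TRF replicates 1 and 3, and that of TRF+H2O2+TRF and TRF joined their replicates 1 and 3. With the replicate block, 1287 probe sets had an unadjusted p under 0.05 for H2O2 against control, where 2 of the 16 splits that part every pair gave as many and the highest other gave 1377. For TRF+H2O2+TRF against TRF it was 874, where 1 of 8 gave as many and the highest other gave 873. The splits that part every pair are too few for a share under 0.05 in both comparisons.

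TRF+H2O2+TRF replicate 4, which had the F42A10.7 signal of 243, was scored over the 20 genes with the smallest p between TRF and control, of which 1 passed over all genes. The score is the mean log2 value of these genes, each relative to its mean in the H2O2 arrays. Signs were set so that a positive score points the way TRF differs from control. The array had a score of -0.20. The H2O2 arrays had -0.24 to 0.39 and the other TRF+H2O2+TRF arrays 0.66, 0.056 and 0.21. A wrong label on this array cannot be told apart from a weak TRF difference in its group, since 2 of the other 3 arrays also lie within the range of the H2O2 arrays, and this doubt bears on every TRF+H2O2+TRF value. Poor quality is argued against, since the mean correlation of the array with the others was 0.969, where the median of the 18 arrays was 0.964. A processing batch shared by the arrays numbered 4 stays open: over 20 genes chosen without these arrays, TRF replicate 4 had 0.394, within the range of the H2O2 arrays (-0.281 to 0.426), whose highest was H2O2 replicate 4. No biological explanation was tested.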

How the results depend on the processing

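The replicate block of numbers 1, 2 and 4, and for lists the median centring, pseudocount, replicate block, exact permutation and single arrays left out, were chosen after the data were seen, as were all tests of the 9 pairs, while the other alternatives were planned. Of the named genes under the limma alternatives, 2929 values kept their direction and side of the threshold or moved by less than the spread, 29 moved further and 6 came past the threshold. The methods' t-test is not in this tally, and F42A10.7 lost its call there. Of the called lists, 482 values kept their call, 287 kept the direction without the call and 3 reversed. The methods' t-test at an unadjusted p under 0.05 gave 401 probe sets for H2O2 against control, 561 for TRF against control, 366 for TRF+H2O2+TRF against H2O2, 444 against control and 251 against TRF, and 0 for TRF against control after Benjamini-Hochberg adjustment. In all 5 comparisons 0 lists passed with an estimated correlation, with or without the replicate block, by fry in either form, or by exact permutation of array means, all after adjustment. Quantile normalization gave 5, 8 and 5 lists for H2O2 against control, TRF+H2O2+TRF against H2O2 and TRF+H2O2+TRF against control (in the second, 6 of the 13 called and 2 others), and no filter gave 6 for TRF+H2O2+TRF against H2O2. Quantile normalization also reversed the vitellogenin medians to -0.0282 for H2O2 against control and 0.0193 for TRF+H2O2+TRF against H2O2, and the ribosomal median to 0.00383 for TRF+H2O2+TRF against control. For TRF against control the replicate block gave 1 probe set, and the block with number 3 left out as well gave 25 (16 higher, 9 lower, with fat-3, F07C3.9, clec-70, thn-1 and clec-65 among them), though the numbers do not pair these arrays throughout, and median centring gave 2. Lists for TRF against control were 9 with median centring, 9 with the replicate block, 10 with the block of numbers 1, 2 and 4, and 9 without the arrays from the later submission. For TRF+H2O2+TRF against TRF the replicate block gave 1 probe set and 7 lists, and with numbers 1, 2 and 4 it gave 0 and 10. Over the 9 pairs the count of 61 became 7 without a variance trend, 0 without the block and 13 without both deviating pairs. With each array left out, probe sets past the threshold ran from 0 to 0 for H2O2 against control, 1 to 2 for TRF against control, 0 to 0 for TRF+H2O2+TRF against H2O2, 0 to 1 against control, 0 to 0 against TRF and 0 to 0 for the interaction, and from 22 to 65 with each of the 9 pairs left out. Lists ran from 6 to 14, 2 to 11, 6 to 16, 3 to 15 and 2 to 12 for the 5 comparisons in that order. With the shared H2O2 arrays split, the r of -0.458 became 0.133, and with the shared control arrays split, the r of 0.349 became -0.144. The construction removes the shared arrays but not the deviations that arrays of equal number share. The cause of the other changes was not tested. Of the 22548 probe sets, those below a geometric mean signal of 47 were not tested, except where no filter was used.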

Other observations

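All tests of this part were chosen only after the results were seen: the paired comparison was added when a replicate block gave 12 probe sets for H2O2 over all 18 arrays, where the additive fit without it gave 0 (412 at an unadjusted p under 0.05 in limma) and 0 for TRF (770).

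Muscle transcripts were higher when each H2O2-exposed array was compared with the unexposed array of its own number, over the 5 pairs of H2O2 and control and the 4 pairs of TRF+H2O2+TRF and TRF. By the labels the latter also differ in the TRF schedule, until day 3 of adulthood against throughout life, so that "with H2O2" below covers both differences in these 4 pairs. In limma with the pair as a block, 61 probe sets passed (49 higher and 12 lower with H2O2, in 51 genes named by 1 symbol), and 53 of them went the same way in 9 of 9 pairs. The genes that rose included 7 of the 17 of the body wall muscle list: mup-2, a troponin T (log2 fold change 0.66 ± 0.0734 (SE), adjusted p = 0.00151), tnt-2 (0.52), unc-89 (0.50), the paramyosin gene unc-15 (0.42), the troponin I gene unc-27 (0.40) and the myosin light chain genes mlc-3 (0.39) and mlc-1 (0.36). Genes outside the list that encode muscle proteins, named here without a fixed list or a set test, included dim-1 (0.53) and the thin filament gene unc-87 (0.51). The calponin genes cpn-4 (0.48) and cpn-3 (0.43) and the calsequestrin gene csq-1 (0.45) were further ones. Of the other genes, C29F5.1 (0.83), gpx-3 of the glutathione peroxidase family (0.66), nhr-57, a target of the hypoxia factor HIF-1 (0.46), the neuropeptide gene flp-18 (0.42), cex-1 (0.74) and C17H12.10 (1.14) rose. Genes that fell included far-3, a fatty acid and retinol binding protein (-0.74), the sugar transporter gene swt-6 (-0.77), the developmental regulators tab-1 (-0.90), ceh-32 (-0.51), ngn-1 (-0.47) and tbx-43 (-0.63), and cfz-2, a Wnt receptor gene (-0.43). Exchanging the labels within pairs gave as many in 1 of 100 exchanges drawn from 256, the real one included (highest other 2). The choice of the comparison was prompted by H2O2 calls on the same arrays, so this share cannot exclude chance. At an unadjusted p under 0.05 there were 1344 probe sets with 676 expected, 3 of 100 exchanges gave as many, and the highest other gave 1395. The count was 22 without the pair of control and H2O2 replicate 5, 29 without that of number 3, 37, 37 and 29 without the TRF pairs of numbers 2, 3 and 4, 7 without a variance trend, 13 without both pairs that deviate together, and 0 without the block. The 7 and the 13 were all higher with H2O2, so none of the genes that fell passed there.

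The body wall muscle list had a mean shift of 0.28 (SD of pairs 0.152) and was higher in 9 of 9 pairs, with 0.345 in the pairs without TRF and 0.206 in those with TRF. Of its 17 genes, 15 were higher, 7 passed over all genes and 13 when adjusted over the list alone. Its adjusted p was 2.75e-18 with the preset correlation and 0.108 with an estimated correlation, and exact sign flips gave p = 0.00391, the smallest that 9 pairs allow (adjusted p = 0.148). Of the 38 lists, 14 passed with the preset correlation and 0 with an estimated one. The others higher with H2O2 included neurons (median 0.13, adjusted p = 1.29e-06), nlp genes (0.15, 6.90e-06), pharynx (0.26, 0.000430) and antioxidant enzymes (0.049, 0.0322), and histones were lower (-0.12, 0.000234). Ribosomal proteins (0.080, 6.32e-18) and cuticle collagens (0.11, 2.47e-05) were called higher as well. The adjusted p of these lists was 0.385 with an estimated correlation, but 0.424 for the nlp genes and 0.438 for the collagens. The ribosomal mean shift was 0.154 in the pairs without TRF and -0.0105 in those with TRF.

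A shift of bright probe sets is argued against, since the muscle shift lay at percentile 100 of 10000 random lists matched on mean signal (highest 0.147). A lower share of germline that would raise all other tissues alike was compared with the intestine and hypodermis lists. The intestine list had a mean shift of 0.093, was higher in 7 of 9 pairs and was called with the preset correlation (adjusted p = 0.00588). The hypodermis list had a mean shift of -0.012 and was higher in 4 of 9 pairs. The muscle shift exceeded the mean of their shifts by 0.243 (SD 0.112, higher in 9 of 9 pairs, exact sign-flip p = 0.00391). The pharynx and neuron lists, which were not in this test, had mean shifts of 0.201 and 0.155. Muscle was singled out for its shift on these same arrays, so an excess over weaker lists was largely fixed in advance. A lower share of germline and other changes in the share of tissues therefore stay open. RNA integrity is argued against, since the shift at no difference in the 3' to 5' ratio was 0.939 times that without it (0.266 ± 0.0512). Higher transcript levels of muscle genes after H2O2 may account for the pattern, as a hypothesis found and tested on the same 18 arrays. A labelling or handling difference that follows H2O2 in every pair, and the TRF schedule in the 4 pairs with TRF, were not tested. Worm stage and the share of embryos were not tested either, and the sperm list differed within the pairs by -0.775 to 1.49 log2. The embryo zygotic list was higher in 1 of 9 pairs (median -0.087, adjusted p = 0.186 with the preset correlation). Across 10286 genes, which are not independent replicates, the H2O2 fold changes of the pairs without TRF and with TRF had an r of 0.181 (exact p = 0.0859 over 256 exchanges, highest other 0.264), which does not decide whether they share a response.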
